A study of Ovis aries with 6 samples.

How the data were processed

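Libraries of sheep oocytes (strain given as Xinjiang Sheep) at the GV and MII stages were analysed, 3 per stage. Per the labels' protocols, MII oocytes were matured at 38.5 °C in 5% CO2, ribosomal RNA was removed from 3 µg of total RNA per sample, libraries were made with a strand-specific NEBNext Ultra kit, and paired reads of 100 bp were sequenced on an Illumina HiSeq instrument. The stated input is large for pools of 30 to 35 oocytes, and whether RNA was amplified, which can change relative counts, is not given in the sources used here. Per the submitters' processing notes, Trimmomatic 0.38, STAR 2.7.1a, StringTie 2.0, featureCounts 1.6.4 and DESeq2 were used, with the Oar_v3.1 genome build. The role and order of these tools, the libraries used for transcript assembly, the strand setting of the counting and its treatment of overlapping or multiply aligned reads are not given in the sources used here. Reads from overlapping or antisense features and from near-identical copies may therefore be shared between identifiers.

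The values are whole-number counts per feature as deposited by the authors, without normalization, in 1 table of 6 libraries. Columns were assigned to libraries by stage and replicate number. Identifiers were looked up in a reference table for the assembly ARS-UI_Ramb_v3.0, in which none of 35057 genes carries an Ensembl identifier, and 0 of 18914 matched. The 23 gene lists fixed before the data were examined, the counts of long non-coding RNAs and the pairs of such RNAs with neighbouring genes were therefore not analysed here. The division into annotated genes and assembled loci took their place and was chosen after the data were seen.

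Differences were tested with edgeR 4.0.16 in R 4.3.3. Features passing filterByExpr were kept (19302), libraries were scaled by the trimmed mean of M-values (TMM), and a quasi-likelihood F-test with robust dispersions compared MII with GV, coded MII minus GV. Adjusted p-values are Benjamini-Hochberg values over all tested features. The standard error (SE) of a log2 fold change is an approximation, its absolute value over the square root of the F statistic. It is not an output of the fit. TMM factors were 1.16 to 1.17 in the GV libraries and 0.899, 0.910 and 0.769 in the MII libraries. CPM values are those of edgeR, on TMM-scaled library totals. Principal components and correlations used log2 CPM with a prior count of 2. Set tests used camera and fry of limma 3.58.1. The number of features at a common depth is the expected number with at least 1 count in a subsample of each library. Values of single measures were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

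The rule for named features, fixed before the data were examined, took the largest changes in each direction among features with a gene symbol, an adjusted p under 0.05, groups that did not overlap and at least 10 CPM in the higher group. The symbol could not be required, and 2 features per direction were named because identifiers stand without names. Ratios of low counts carry exact 95% counting intervals, and a group with 0 counts was set to a floor of 3 counts.

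Alternatives covered 3 other scalings, TMM without the 20 most abundant features, 2 low-count filters, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, a 2-fold minimum, a test against a 1.5-fold change, a replicate block and leaving out each library. The test was run on 5 simulated sets of 19302 features with known changes and the dispersions of these libraries. It recovered 2.15% of features changed 1.5-fold, 21.8% of those changed 2-fold and 83.1% of those changed 4-fold, and 33 of 376 calls (8.78%) were false. Over all 5 sets, 326, 325 and 319 features changed at these sizes passed the filter, which was applied again to each set. Recovery is given as a percent of these. The real comparison called 50.9% of features. Recovery and the share of false calls depend on how many features change, so these values do not carry over to the reported test.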

Results

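Total RNA from sheep oocytes was sequenced before and after meiotic maturation. Germinal vesicle (GV) oocytes are arrested in prophase of the first meiotic division with an intact nucleus, and metaphase II (MII) oocytes have released the first polar body and are arrested again in the second division. Each stage had 3 libraries, and each library came from a pool of 30 to 35 oocytes out of follicles of 2 to 8 mm. The GV oocytes were collected without cumulus cells. The MII oocytes came from cumulus-oocyte complexes, lost their cumulus by hyaluronidase and were held in maturation medium for 23 to 25 h, so stage, culture and the kind of oocyte at collection changed together. The labels call each pool a biological repeat and do not say whether pools came from different animals, so the p-values measure the spread between these pools. Total counts were 26984892, 27108507 and 28117286 in the GV libraries and 28578411, 31291218 and 31962405 in the MII libraries.

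The count table held 25609 features of 2 classes. There were 18914 Ensembl sheep genes (annotated genes) and 6695 loci with the MSTRG identifiers that StringTie gives to transcripts it assembles (assembled loci). The files do not pair the identifiers with gene names, and none of the 18914 gene identifiers could be matched to a symbol. Features are therefore described by class and abundance, without chromosome positions, and no assembled locus is called a long non-coding RNA.

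GV and MII oocytes had separate RNA profiles. Over 19302 tested features, the first principal component of log2 CPM carried 71.5% of the variance, with the GV libraries between −79.7 and −77.6 and the MII libraries between 54.4 and 105.1. Pearson correlations across features, which are not independent replicates, were 0.979 to 0.984 between GV libraries, 0.962 to 0.970 between MII libraries and 0.888 to 0.928 between stages. MII oocyte pools varied more than GV pools. The biological coefficient of variation was 0.323 in MII and 0.191 in GV, and any pair of MII libraries (0.299 to 0.358) exceeded any pair of GV libraries (0.167 to 0.205). No libraries were identical, and none was counted as a repeat of another, since pairs within a stage had chi-square values of 18.0 to 75.1 per degree of freedom, a check against counting error only.

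**Figure D1:**
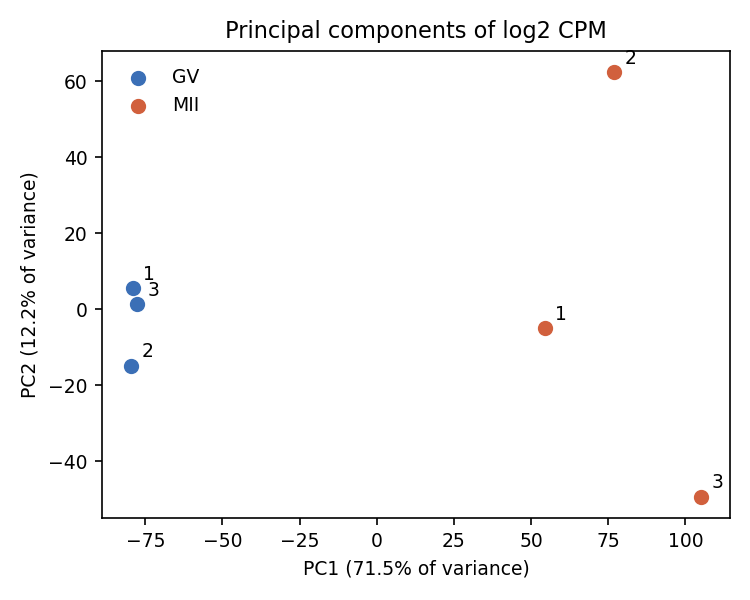
Principal components 1 and 2 of log2 CPM over 19302 features, with the percent of variance on each axis and each point a library of GV or MII oocytes. The 3 MII libraries spread from 54.4 to 105.1 on the first axis, and the 3 GV libraries lie between −79.7 and −77.6.

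The comparison of MII with GV oocytes asks which RNAs change in relative level as the oocyte completes maturation. Of the tested features, 4769 were higher and 5057 lower in MII (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 50.9%. Large decreases outnumbered large increases: 1272 features fell and 239 rose at least 4-fold, and 206 fell and 50 rose at least 8-fold. The 3 values of one stage all lay above those of the other for 11635 features (60.3%), where chance gives 10%. Levels are relative to each library, since no measure of RNA per oocyte was used here. With scaling by the total count alone, 2332 features were higher and 7140 lower (24.6% of calls higher, against 48.5%), and the median log2 fold change over all features was −0.45 rather than −0.01. Upper-quartile scaling gave a median of −0.11.

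Assembled loci fell more often, and rose less often, than annotated genes. Among 12854 tested annotated genes, 4056 (31.6%) rose, 2619 (20.4%) fell and 6179 did not pass, with a median log2 fold change of 0.25. Among 6448 assembled loci, 713 (11.1%) rose, 2438 (37.8%) fell and 3297 did not pass, with a median of −0.50. Of the loci that changed by at least 4-fold, 623 fell and 32 rose, while 649 annotated genes fell and 207 rose. Rising calls were 60.8% of the calls among annotated genes, a majority that flipped to 35.4% with scaling by total count alone. Among assembled loci they were 22.6%, and 7.23% with that scaling. The median of annotated genes was then −0.19 and that of assembled loci −0.94. The count of rising assembled loci was 458 without GV replicate 3. As a set chosen after the data were seen, assembled loci ranked lower than the other features by camera with a preset correlation of 0.01 (p = 7.67e-09). The camera p was 0.103 with an estimated correlation, of 0.0766, so that call was lost, and limma's fry, which asks only whether the loci move one way, gave p = 0.00655.

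Abundant RNAs were called higher in MII more often than scarce RNAs. The difference between deciles was not tested, and calls also depend on power, which is lower at low counts. In the decile of features with the highest mean level (108 to 11899 CPM), 58.6% were higher and 14.4% lower in MII, with a median log2 fold change of 0.64. In the decile with the lowest level (0.265 to 0.817 CPM), 5.59% were higher and 26.3% lower, with a median of −0.51. That direction flipped in limma-voom with quantile normalization, to 16.4% higher, 11.2% lower and a median of 0.06. This setting changed the test along with the scaling. Quantile normalization gives every library the same distribution of values, so it can remove a shift tied to abundance by construction. The highest decile kept a positive median under 5 other scalings, down to 0.18 under quantile normalization, where 37.3% were higher and 24.7% lower. With scaling by total count alone, 36.8% of it was higher and 24.3% lower, and 2.49% and 35.7% of the lowest decile. Assembled loci had a lower median than annotated genes in 10 of 10 abundance deciles, with differences between −1.12 and −0.46 on the log2 scale. In the most abundant decile, 61.8% of annotated genes and 35.2% of assembled loci rose, and 13.5% and 21.0% fell.

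**Figure D2:**
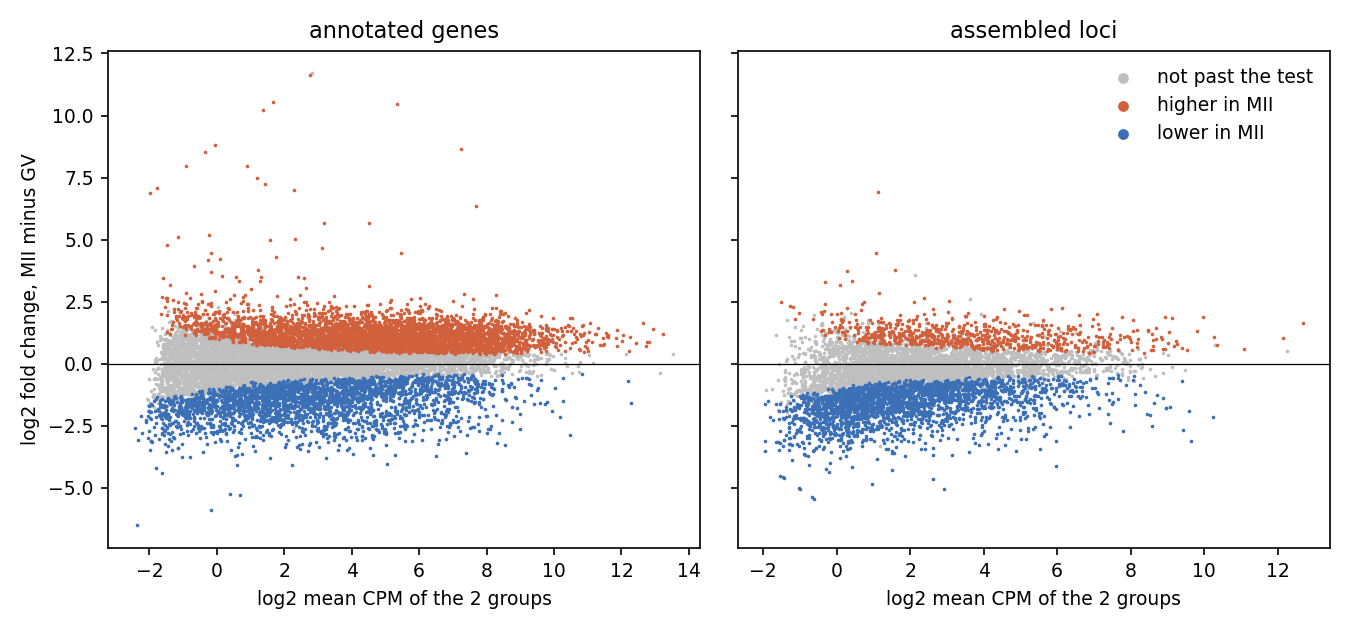
Log2 fold change (MII minus GV) against log2 of the mean CPM of GV and MII for annotated genes and assembled loci, with features past the adjusted threshold coloured. Among assembled loci, 2438 lie in the lower called group and 713 in the higher one.

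**Figure D3:**
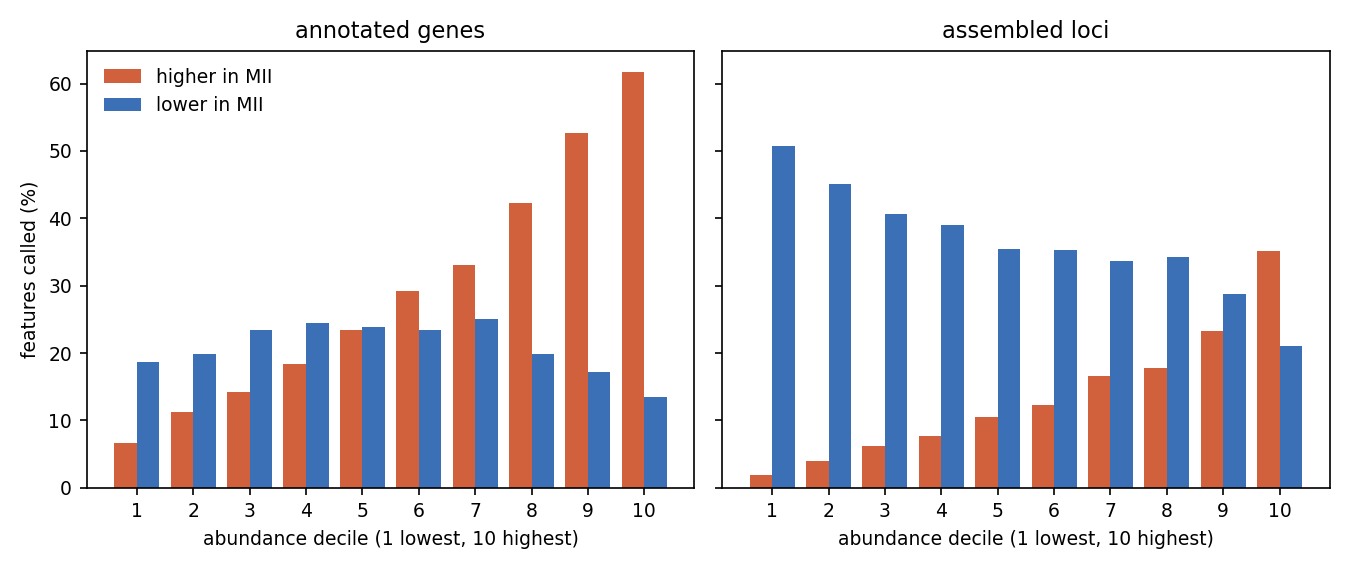
Percent of features higher and lower in MII in each decile of mean abundance, for annotated genes and assembled loci. For annotated genes, the percent higher goes from 6.73 in the lowest decile to 61.8 in the highest.

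MII libraries held a narrower RNA pool. At a common depth of 26984892 counts, 23723 ± 118 features (mean ± SD, n = 3) were detected in GV and 22860 ± 294 (n = 3) in MII. Annotated genes accounted for most of the gap, with 17071 ± 115 detected in GV and 16269 ± 253 in MII. Nearly all of the 6695 assembled loci were detected at both stages (6652 ± 2.91 in GV, 6592 ± 43.7 in MII). They could therefore add little to the gap. The 100 most abundant features took 24.3 ± 0.123% of counts in GV and 28.7 ± 1.42% in MII. The effective number of features (the exponential of the entropy of count shares) was 3329 ± 25.8 in GV and 2537 ± 218 in MII. Assembled loci took 16.3 ± 0.934% of counts in GV and 12.4 ± 1.24% in MII. For each of these measures the stages did not overlap, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow.

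**Figure D4:**
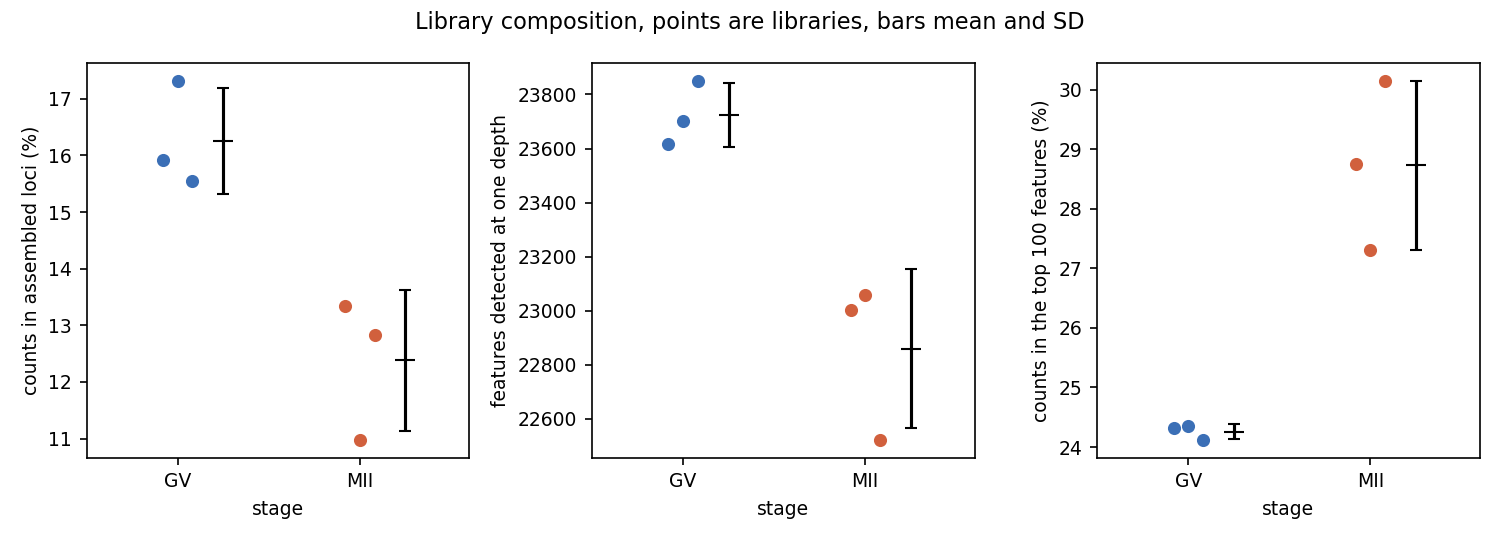
Percent of counts in assembled loci, features detected at one depth and percent of counts in the top 100 features (vertical axes, not starting at 0) for GV and MII, with each point a library and bars for the mean and SD of 3 libraries. Assembled loci took 16.3% of counts on average in GV and 12.4% in MII.

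The largest increases were in annotated genes nearly absent from GV libraries, and the largest decreases in assembled loci, among features of at least 10 CPM in the higher group whose stages did not overlap. ENSOARG00000014971 had 0, 2 and 3 counts in the GV libraries and 2202, 1339 and 2682 in the MII libraries. Its level was 0.0514 ± 0.0468 CPM in GV and 80.7 ± 31.4 CPM in MII (SD, n = 3 each), a ratio of 1516 with a 95% counting interval of 649 to 4669 (edgeR adjusted p = 1.18e-05). ENSOARG00000005315 had 0 counts in each GV library and 325, 269 and 453 in MII, or 13.5 ± 4.56 CPM. With a floor of 3 counts set for the GV group, its ratio of MII to GV was 425 (edgeR adjusted p = 2.92e-05). The exact 95% counting interval used for the other gene starts lower, at 345. MSTRG.23594 went from 14.8 ± 1.59 CPM in GV to 0.447 ± 0.0598 CPM in MII, a log2 fold change of −5.04 ± 0.29 (SE, edgeR adjusted p = 1.18e-05). MSTRG.3955 had 51, 827 and 257 counts in GV and 30, 4 and 3 in MII, a log2 fold change of −4.63 ± 1.24 (SE, edgeR adjusted p = 0.0183). Its value rested on single libraries, at −3.31 without GV replicate 2 and −6.43 without MII replicate 1, and its adjusted p was 0.0744 without MII replicate 2 and up to 0.261 over 19 alternatives. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.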

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

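Quantile normalization, thinning to the lowest total, leaving out assembled loci that match an annotated gene and adjustment over the assembled loci alone were chosen after the data were seen. Counts moved by more than 1.5 times under few settings, and no feature called in both a setting and the reported test changed sign. A feature that lost its call does not enter that comparison of signs. Of the 9826 reported calls, 7387 were kept with scaling by total count alone and 8023 in limma-voom with quantile normalization. Scaling by total count alone gave 2332 features and 262 assembled loci higher in MII. A 2-fold minimum gave 2809 and 411, and a test against a 1.5-fold change gave 2600 and 319, both stricter by construction. A filter of 5 CPM, which tested 10820 features, gave 3243 lower, with 376 assembled loci higher and 1328 lower. Leaving out each library gave 3632 to 4813 features higher, 4072 to 5119 lower and 458 to 843 assembled loci higher. The cause of the other changes was not tested. The DESeq2 Wald test gave 5103 higher and 4943 lower. MSTRG.3955 lost its call under 5 of 19 alternatives and was not tested under the 5 CPM filter, and the other 3 named features kept sign and call in all 20. The replicate block gave 4094 higher and 4621 lower. Libraries of the same number did not deviate together (correlations −0.0892, −0.230 and −0.0304). Mitochondrially encoded genes could not be identified by name, so it is not known which of them the scaling without the top 20 features left out. Alternatives for gene lists, long non-coding RNAs and neighbouring pairs were not run, because the reference used here gave the identifiers no names, types or positions. Those for normalized units did not apply to counts. At the lowest library total, thinned counts gave 4747 higher and 5048 lower.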

Other observations

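The tests of a trend with abundance, of mixing at the share that rising features need, of chance similarity between features and of neighbouring locus numbers were chosen after the results were seen. Those of the share of assembled loci rest on a division into classes that was also chosen after the data were seen. The most abundant RNAs were largely the same at both stages. Of the 20 features with the highest mean level, 18 were shared between GV and MII, as were 73 of the top 100 and 733 of the top 1000. Pairs of GV libraries shared 90 to 93 of their top 100 features, pairs of MII libraries 86 to 92, and pairs from different stages 68 to 74. Assembled loci made up 125 of the top 1000 in GV and 87 in MII. Features called higher in MII held 45.5 ± 0.365% of GV counts and 68.7 ± 2.89% of MII counts, and features called lower held 23.3 ± 0.373% and 6.99 ± 1.32% (SD, n = 3). These groups were chosen on the same libraries.

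Across assembled loci, fold changes of loci with nearby numbers were weakly correlated, over 7 distances tested. Pearson r was 0.0821 for numbers 1 apart (Spearman rho 0.0718, permutation p = 3e-04, adjusted 0.00105), 0.0624 for 2 apart (rho 0.0577, p = 0.0047, adjusted 0.011), 0.0923 for 3 apart (rho 0.0809, p = 1e-04, the smallest that 10000 shuffles can give, adjusted 7e-04) and 0.0564 for 5 apart (rho 0.0749, p = 0.017, adjusted 0.0298). It was 0.0341 for 10 apart (rho 0.0412, p = 0.141, adjusted 0.197), −0.00261 for 50 apart (rho 0.00298, p = 0.913, adjusted 0.913) and 0.00826 for 100 apart (rho 0.00186, p = 0.745, adjusted 0.869). Loci are not independent replicates.

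Of the 10 splits of the 6 libraries into 3 and 3, the real one called 9826 features, and 1 split, the real one itself, gave a count that large. The highest of the other splits was 0 by edgeR, with 93 to 318 features at an unadjusted p under 0.05. Each of the other splits put libraries of both stages in each group, so the stage difference counted as spread within groups. Few calls could follow from them, and their 0 is no measure of chance. With 10 splits the share cannot go under 0.1. The GV oocytes were collected bare, and hyaluronidase removed the cumulus of the MII oocytes, so cumulus cells left behind could add RNA at either stage. Of the cumulus markers, 0 could be matched to a feature, so more cumulus cell RNA in the GV libraries and a change within the oocyte cannot be told apart here.

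Assembled loci took a smaller share of counts in MII, whose libraries had the higher totals. A few abundant features taking the counts would close the gap once they are removed, but without the 200 most abundant features it was 4.99 percentage points (19.7 ± 0.949% against 14.7 ± 1.54%, SD, n = 3). Reads shared with annotated genes stay open: the median log2 fold change of assembled loci minus that of annotated genes went from −0.75 to −0.78 without 193 loci of at least 600 counts in total that lie within 10% of a gene's count in every library, but such a match does not identify shared reads, and loci with fewer counts were not searched. A change with stage or culture may explain the pattern and was not tested separately, and an assembly drawn mainly from GV reads, whose input libraries are not given in the sources used here, stays open.

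The MII libraries differed from each other in part along the axis from GV to MII. The difference between a pair of them was regressed across features on the change in the remaining one from GV. Slopes were 0.199 for library 3 minus 1, 0.156 for 3 minus 2 and 0.0680 for 2 minus 1. Between GV libraries they were −0.0211 to 0.0122. Correlations across features were 0.325, 0.193 and 0.130 for the MII pairs in that order, so this change accounted for little of their differences. On the second principal component (12.2% of variance), MII libraries 2 and 3 lay apart, at 62.4 and −49.3. A straight-line trend with abundance did not account for the slope of library 3 minus 1, which was 0.186 with mean abundance in the model. The slopes of 3 minus 2 and 2 minus 1 were then 0.133 and 0.0749. A curved trend was not tested. RNA of GV-type oocytes mixed into MII library 1 was predicted to lower its rising features by a common factor, for a slope near 0 among them. The slope was 0.0436 (95% bootstrap interval −0.0209 to 0.106). A common factor holds only for features nearly absent from GV, since mixing lowers features with a smaller rise by less. Mixing could thus also give a positive slope, so this test cannot decide. These features need a share of 19.4%, and 68 of 7887 features with at least 10 CPM in GV lay below it in library 1, which decides nothing, since that bound covers counting error only and takes the GV mean as the profile of the mixed-in RNA. Such mixing and less advanced maturation across that pool cannot be told apart, and no biological explanation was tested. Among features at least 2-fold lower in library 2, the slope of library 3 minus 1 was 0.162 (95% bootstrap interval 0.114 to 0.205). No prediction had been made for them. Mixing was examined for library 1 only. Library 3 had the lowest TMM factor (0.769, against 0.899 and 0.910 in libraries 1 and 2). It also had the fewest features at the common depth (22523, against 23001 and 23057). Which library stood apart was not tested.

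Some assembled loci had nearly the same counts as an annotated gene. Among features with at least 2000 counts in total, 7 pairs of a locus and a gene were within 1% in every library, with totals of 6348 to 85471 and a largest difference of 1 to 32 counts in any library. Chance similarity of unrelated features would also pair annotated genes with each other, and 0 such pairs were found. Reads counted under both identifiers are a candidate explanation, which was not tested without positions. At the same minimum of 2000 counts, 21 locus and gene pairs stood beside 13 pairs of annotated genes within 5%, and 174 beside 613 within 10%, out of 9702364 and 17202045 possible pairs, so the excess was seen within 1% and 5% and not within 10%.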
